A study of Mus musculus with 12 samples.

How the data were processed

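Poly(A) RNA of OCY454 cells was sequenced in 12 libraries, 2 for each of 6 groups formed by genotype (WT and KO) and day at 37 °C (1, 14 and 28). Per the labels, the cells were kept at 33 °C in alpha-MEM with 10% serum and 1% antibiotic, moved to 37 °C to differentiate in 12-well plates and lysed in Qiazol. Between 400 and 1000 ng of RNA per sample went into poly(A) selection and library preparation. The deposited values were read counts per gene. Per the submitters' processing notes, reads were aligned with STAR to the mouse build mm10 and counted with featureCounts of the Subread package, and edgeR was named without a version or a stated role. The gene annotation, the strand setting of the counting and the handling of reads that map to several places are not given in the sources used here.

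The table held 32248 rows, of which 9345 had no count in any library, and all 12 library columns were used (0 columns were left out). The table also held 3 transgene rows, for a red fluorescent protein, a fusion of YAP with a green fluorescent protein and Cre recombinase, which were kept out of the tests and of the description of the libraries. Gene positions, exons, transcript lengths and overlaps were read from a GRCm38/mm10 annotation that carried the symbols of 97.6% of the rows and of 99.2% of the genes tested. With the strand setting not given, the table cannot show whether reads of an overlapping gene on the opposite strand were included in the counts of Piezo1 and Slc2a1 and of Abi3, Adgrg2, Aldoa, Ankrd37, Axin2, Bnip3, Ccn2, Cd34, Cyp51, Ddit3, Fosl1, Hmgcs1, Hoxb5, Hoxd3, Hoxd4, Il12rb2, Ildr2, Irf7, Jun, Lama2, Lama3, Lef1, Loxl2, Lrp3, Lss, Map2, Ndrg1, Ostn, Palm3, Phospho1, Runx2, S1pr3, Sfrp2, Shank1, Smpd3, Tagln, Tenm3, Txnip, Unc5c and Yap1. Total counts ran from 8590132 to 15357433 per library.

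Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the 6 groups (minimum count 10, minimum total 15), which left 13772 genes. Libraries were scaled by TMM, and a quasi-likelihood negative binomial model with 1 coefficient for each of the 6 groups was fitted to all 12 libraries with 6 residual degrees of freedom, 14.6 prior degrees of freedom and a common biological coefficient of variation of 5.53%. Each of 11 comparisons was tested with the quasi-likelihood F test, two-sided, and p-values were adjusted over the genes tested by the Benjamini-Hochberg method. A gene counts as called when its adjusted p is below 0.05. The 11 comparisons were KO minus WT at each day, the changes between days in each line, and the differences between the lines in their changes from day 1 to day 14 and from day 1 to day 28. Each standard error is the log2 fold change divided by the square root of its F statistic. CPM are the edgeR cpm values on the TMM-scaled library totals, given as the mean with the standard deviation (SD) over 2 libraries.

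For genes with 0 counts in the lower group, the fold is a bound computed with 3 counts in place of 0. With 1 to 3 counts in the lower group, the ratio is given with its exact binomial 95% interval. These intervals and floors cover counting error only. List medians are as printed with such genes at their bound or ratio.

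A set of 28 gene lists was tested in every comparison with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. The lists hold osteocyte markers, osteoblast and bone matrix genes, osteoclast-regulating factors, perilacunar remodelling genes, mechanosensitive channels and connexins, YAP/TAZ target genes and immediate early genes. They also hold Wnt/beta-catenin target genes, secreted Wnt ligands and inhibitors, Notch pathway genes, BMP and TGF-beta target genes, and collagen processing and cross-linking genes. Further lists cover actin and focal adhesion genes, dendrite and axon guidance genes, cell cycle genes, p53 target genes, interferon-stimulated genes, NF-kB inflammatory genes, unfolded protein and integrated stress response genes, cholesterol biosynthesis genes, and glycolysis and hypoxia genes. The rest are markers of chondrocytes, adipocytes, skeletal muscle, blood cells, endothelium, and fibroblasts and tendon, and the mitochondrially encoded genes. For each list, the members called over all genes were counted, and again with p-values adjusted over the list alone.

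The lists, comparisons, tests and alternatives were fixed before the data were examined, except the removal of chromosome medians and any test or alternative said below to be chosen later. Genes are named by rule. The rule names Piezo1 and the measured members of the osteocyte and osteoblast lists. For the 3 comparisons of KO with WT and for day 28 minus day 1 in each line, it names the 8 highest and 8 lowest log2 fold changes among called genes with an average log2 CPM of at least 1 and no overlap of the libraries in CPM. For the differences of change it names the 5 highest and 5 lowest without the overlap criterion, and for genes called in 1 direction on all 3 days the 8 per direction with the largest smallest change. It also names the 4 members of each list with the smallest adjusted p in each comparison. Predicted and clone-named gene models were passed over. Genes named outside this rule are said to be chosen after their values were seen.

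Alternatives were DESeq2 1.42.0 size factors, library totals without TMM, the DESeq2 Wald test, no count filter, a filter of CPM of at least 1 in at least 2 libraries, the replicate number as a block, a fit to only the libraries compared, and leaving out each library in turn. For the lists they were camera with an estimated correlation, camera with the block, and fry. Camera with the estimated correlation alone, camera with the residual degrees of freedom alone and the gene families under other scalings were added after the data were examined. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

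Test simulations changed 200 genes and shifted chromosome 2 by log2 0.4 in KO minus WT. At day 1 edgeR recovered 65.7% of genes changed 1.5-fold, 86.6% of those 2-fold and 95.5% of those 4-fold. Of its calls, shifted genes included, 4.77% were unchanged. Without change it called 0 to 4 of 13772 genes. Of 27 unchanged lists camera called 0 and fry 1 (correlated genes untested).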

Results

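OCY454 is a mouse osteocyte-like cell line with a temperature-sensitive large T antigen, so it divides at 33 °C and differentiates at 37 °C. Cells in which exons 19 to 21 of Piezo1 had been deleted with CRISPR-Cas9 (libraries labelled KO) were compared with unedited cells (WT). Poly(A) RNA was sequenced after 1, 14 and 28 days at 37 °C with 2 libraries per line and day. Piezo1 encodes a mechanically gated cation channel of the plasma membrane, and the comparisons ask how its loss alters gene expression as the cells differentiate. All log2 fold changes below come from the edgeR fit to the 12 libraries, with n = 2 per group, and are printed with their standard error after ±. The adjusted p of a gene list is that of camera over the 28 lists. The labels do not say that the replicates are separate cultures or how many edited clones were used, so the p-values measure only the spread between these samples.

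Total counts were 14696791 and 14509593 in WT at day 1, 11801796 and 8590132 at day 14, and 14150450 and 12021145 at day 28. The KO libraries held 11629059 and 13479128, 10868159 and 11927860, and 12283357 and 15357433. TMM factors lay between 0.9417 and 1.051, mitochondrially encoded genes took 1.12% to 2.31% of the counts, and the 20 most abundant genes took 7.2% to 11%. Replicates differed most at day 28. Of the genes with at least 10 CPM, 154 of 9326 in WT and 54 of 9083 in KO differed by more than 1.5-fold between the replicates of day 28, against 3 of 9305 in WT and 2 of 9227 in KO at day 1.

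The first principal component carried 47% of the variance over the genes tested and separated the lines, from -56.4 to -19.3 in WT and from 15.2 to 58.7 in KO. The second carried 24% and ordered the libraries by day within each line.

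**Figure D1:**
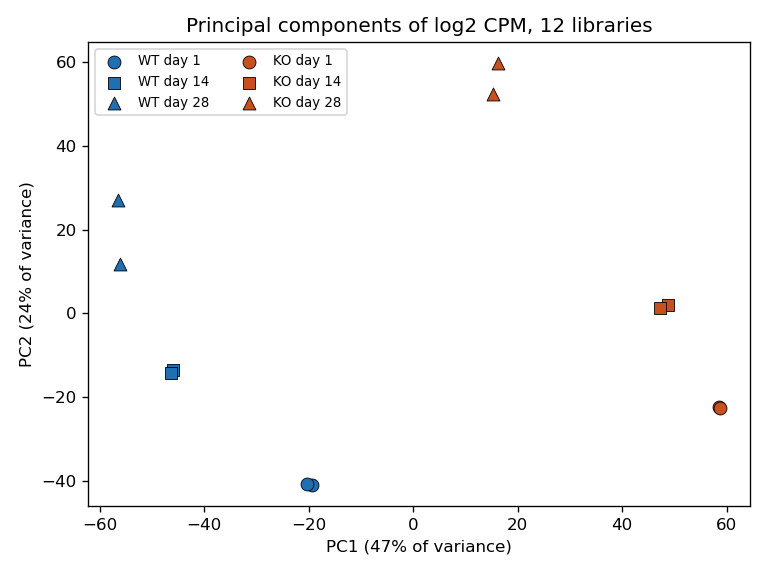
Scores of the 12 libraries on the first and second principal components of log2 CPM, with 1 point per library coloured by line. WT libraries lie between -56.4 and -19.3 and KO libraries between 15.2 and 58.7 on the first component, which carries 47% of the variance.

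Piezo1 (ENSMUSG00000014444.17, chromosome 8, 122481698 to 122551329, minus strand, GRCm38/mm10) was abundant in every library. WT libraries held 3323 and 3268 counts at day 1, 2499 and 1781 at day 14, and 3369 and 2929 at day 28. Libraries labelled KO held 1988 and 2302, 1211 and 1255, and 3254 and 4058. The Piezo1 mean in WT was 215.3 ± 1.13 CPM (SD, n = 2) at day 1, 208.4 ± 3.25 at day 14 and 238.5 ± 4.73 at day 28. In KO it was 169.6 ± 0.323, 110.9 ± 4.76 and 278.5 ± 4.19 CPM. The KO minus WT log2 fold change of Piezo1 was -0.34 ± 0.06, adjusted p = 9.07e-05 at day 1 and -0.91 ± 0.06, adjusted p = 1.52e-10 at day 14. At day 28 Piezo1 counts were higher in KO, by 0.22 ± 0.06, adjusted p = 0.00418. Within the KO line Piezo1 fell from day 1 to day 14 (-0.61 ± 0.06, adjusted p = 1.33e-07) and rose from day 14 to day 28 (1.33 ± 0.06, adjusted p = 2.26e-13), while its change from day 1 to day 14 in WT was not called (-0.05, adjusted p = 0.586). The change of Piezo1 from day 1 differed between the lines by -0.57 ± 0.09, adjusted p = 7.86e-05 at day 14 and by 0.57 ± 0.08, adjusted p = 4.76e-05 at day 28.

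The deletion leaves most of the Piezo1 transcript countable. Exons 19 to 21 lie between 122495417 and 122496579 and hold 504 of the 8216 nucleotides of the 51-exon transcript, or 6.13%. They amount to 168 whole codons (remainder 0), so joining exon 18 to exon 22 keeps the reading frame. The count of the gene therefore barely checks the labels, and the table has no exon counts. Ctu2 overlaps Piezo1 on the opposite strand, and the strand setting of the counting was not given.

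**Figure D2:**
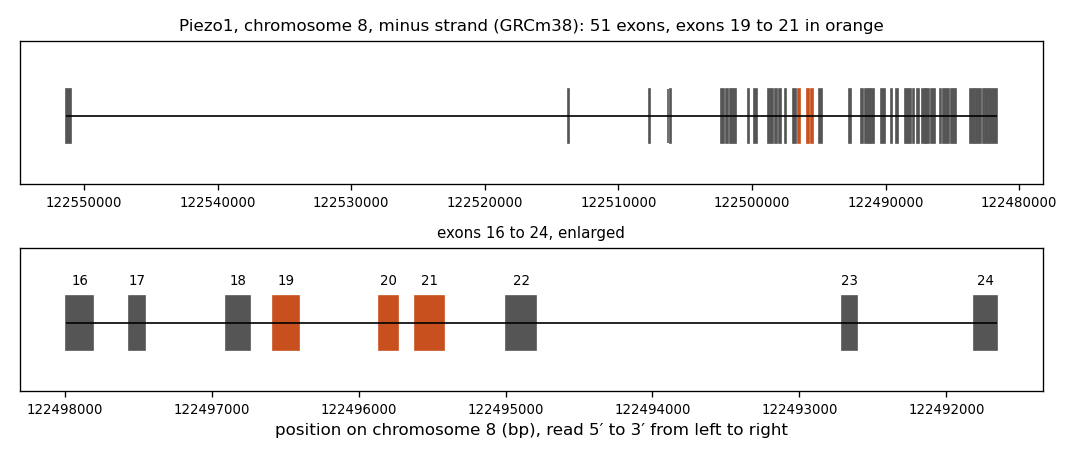
Exon map of Piezo1 on chromosome 8 (position in base pairs, GRCm38/mm10, minus strand), with boxes for the 51 exons, the deleted exons 19 to 21 in orange and a second panel that enlarges the region around them. The deleted exons hold 504 of 8216 nucleotides, or 6.13% of the transcript.

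At day 1 the lines already differed in 5544 of 13772 genes, 2685 higher and 2859 lower in KO. The glucose transporter gene Slc2a1 was lower in KO (-2.29 ± 0.10, adjusted p = 4.9e-13). A second stretch-gated channel gene, Piezo2, was nearly lost (-4.93 ± 0.19, adjusted p = 2.78e-14), and several developmental transcription factors of the Hox and Zic families were higher. Changes of more than 2-fold were 305 higher and 973 lower. With library totals only in place of TMM the split was 2121 higher and 3418 lower of 5539 called, so the balance of directions at day 1 depends on the scaling.

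The highest log2 fold changes at day 1 were those of the patterning gene Hoxd4 (5.29 ± 0.47, adjusted p = 1.66e-08), the death-associated kinase Dapk1 (4.75 ± 0.26, adjusted p = 7.97e-12), Mapt (4.11 ± 0.27), Hoxd8 (4.02 ± 0.26), the zinc finger factor Zic2 (3.99 ± 0.34), Ror1 (3.89 ± 0.27), the Wnt inhibitor Sfrp1 (3.76 ± 0.14, adjusted p = 2.4e-14) and Adam23 (3.58 ± 0.13). Hoxd4 (ENSMUSG00000101174.8, chromosome 2, 74711929 to 74729160) overlaps Hoxd3 on its own strand and Hoxd3os1 on the opposite one, and the table does not show from which gene the reads in the overlap came. The lowest were genes with almost no reads in KO. Tmod2, which encodes an actin-capping tropomodulin (ENSMUSG00000032186.15, chromosome 9, 75565621 to 75611325), was at least 87.9-fold lower, and the channel gene Hcn2 was at least 51.2-fold lower. Alx1, a craniofacial homeobox gene, was at least 50.1-fold lower, Aplp1 at least 38.8-fold, Bmp8a at least 32.5-fold and Acot6 at least 29.5-fold. Zmym6 was 910-fold (95% interval 163 to 36000) lower and Ildr2 596-fold (95% interval 107 to 23600) lower.

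Of the 19 glycolysis and hypoxia genes at day 1, 0 were higher, 17 lower and 2 not called, with a median log2 fold change of -1.58 (adjusted p = 6e-29, adjusted p = 0.11 with an estimated correlation). Vegfa (-1.72 ± 0.06, adjusted p = 2.55e-14), the mitophagy receptor Bnip3 (-2.46 ± 0.14) and Ndrg1 (-1.55 ± 0.09) were among them. Collagen processing and cross-linking genes moved the same way. Of 16, 1 was higher, 10 lower and 5 not called (2 and 10 adjusted over the list alone), with a median of -0.35 (adjusted p = 2.2e-06, adjusted p = 0.33 with an estimated correlation), led by the prolyl hydroxylase P4ha1 (-1.95 ± 0.13, adjusted p = 2.3e-10), Loxl2 (-1.94 ± 0.12) and the lysyl hydroxylase Plod2 (-0.96 ± 0.07). Of 17 unfolded protein and integrated stress response genes, 1 was higher, 13 lower and 3 not called, with a median of -0.43 (adjusted p = 1.3e-06, adjusted p = 0.034 with an estimated correlation). The lower members included Trib3 (-1.57 ± 0.07, adjusted p = 4.34e-13), Ddit3 (-1.08 ± 0.08) and Asns (-0.68 ± 0.07). This was the only list at day 1 whose call held with an estimated correlation. BMP and TGF-beta target genes (2 higher and 8 lower of 16, median -0.39, adjusted p = 0.001, adjusted p = 0.2 with an estimated correlation) were lower through Inhba (-1.54 ± 0.08) and Skil (-1.22 ± 0.09).

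Cell cycle genes were higher in KO at day 1. Of 24, 15 were higher, 2 lower and 7 not called (15 and 3 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.0012, adjusted p = 0.24 with an estimated correlation), and Plk1 (0.83 ± 0.09), Cenpf (0.75 ± 0.07) and Mki67 (0.43 ± 0.06) were examples. Actin and focal adhesion genes were mostly higher (12 higher and 2 lower of 20, 13 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.0022, adjusted p = 0.52 with an estimated correlation), as in Acta2 (0.88 ± 0.07, adjusted p = 4.49e-09) and Myl9 (0.73 ± 0.08), whereas calponin 1, Cnn1, was lower (-3.35 ± 0.40). Mitochondrially encoded genes were higher (9 higher and 0 lower of 12, median 0.61, adjusted p = 0.0053, adjusted p = 0.47 with an estimated correlation), among them mt-Nd1 (0.85 ± 0.10, adjusted p = 9.24e-07). The p53 target genes were called higher (10 higher and 4 lower of 19, 12 and 4 adjusted over the list alone, adjusted p = 0.0091, adjusted p = 0.17 with an estimated correlation) with a positive median of 0.26 but a negative mean. Trp53inp1 (1.48 ± 0.08) and Phlda3 (1.40 ± 0.10) were higher, against Perp, which was 78.5-fold (95% interval 21.4 to 653) lower. Wnt/beta-catenin target genes were called higher (6 higher and 2 lower of 13, 7 and 2 adjusted over the list alone, median 0.48, adjusted p = 0.039, adjusted p = 0.52 with an estimated correlation), with Apcdd1 (1.76 ± 0.11) and Nkd1 (1.17 ± 0.11) higher and Nkd2 (-3.86 ± 0.25) and Lgr6 (-2.81 ± 0.27) lower.

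Secreted Wnt ligands and inhibitors were called higher at day 1 (4 higher and 0 lower of 14, adjusted p = 0.014, adjusted p = 0.52 with an estimated correlation) although their median was -0.05. The members that moved were the inhibitors Wif1 (1.28 ± 0.16), Dkk3 (0.64 ± 0.07) and Sfrp1 (3.76) and the ligand Wnt5b (0.64, not called at 0.53 without KO day 1 replicate 1). NF-kB inflammatory genes were lower (0 higher and 5 lower of 10, median -0.48, adjusted p = 0.04, adjusted p = 0.24 with an estimated correlation). Tnfaip3 was at -1.11 ± 0.17 and Cxcl1 at -1.44 ± 0.24. Chondrocyte markers were lower (2 higher and 6 lower of 10, median -1.17, adjusted p = 0.0053, adjusted p = 0.33 with an estimated correlation). Hapln1 was at -3.22 ± 0.21 and Sox6 at -3.12 ± 0.21.

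Osteocyte markers were not called as a list at day 1 (4 higher and 2 lower of 13, camera adjusted p = 0.43). Phex, a mineralization gene, was higher (1.01 ± 0.20, adjusted p = 0.000396) and the chemokine scavenger Ackr3 lower (-3.27 ± 0.43, adjusted p = 3.14e-06), while Dmp1 (-0.34, adjusted p = 0.319) and Sost (-0.46, adjusted p = 0.494) were not called. Osteoblast and bone matrix genes split 4 higher and 6 lower of 18 (adjusted p = 0.68), with Ibsp lower (-1.16 ± 0.13), Bglap2 higher (1.04 ± 0.18) and Runx2 not called (0.02, adjusted p = 0.911). The 16 mechanosensitive channels and connexins also split (7 higher and 4 lower of 16, 7 and 6 adjusted over the list alone, adjusted p = 0.97), with P2rx7 (1.30 ± 0.10) higher and Piezo2 (ENSMUSG00000041482.17, chromosome 18, 63010213 to 63387183), Pkd2 (-0.44 ± 0.06) and Piezo1 lower. YAP/TAZ target genes moved in both directions (7 higher and 9 lower of 22, adjusted p = 0.94). Examples were Ankrd1 (-1.76 ± 0.15) and F3 (0.82 ± 0.12).

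The remaining lists were not called at day 1. Interferon-stimulated genes were 2 higher and 6 lower of 17, 2 and 10 adjusted over the list alone (median -0.45, adjusted p = 0.22), with Oasl2 lower (-1.41 ± 0.19). Dendrite and axon guidance genes were 6 higher and 11 lower of 21, 7 and 11 adjusted over the list alone (adjusted p = 0.32), with Sema3d lower (-4.29 ± 0.16) and Slit2 higher (1.25 ± 0.08). Perilacunar remodelling genes were 3 higher and 1 lower of 9 (adjusted p = 0.079, Mmp2 0.83 ± 0.08), osteoclast-regulating factors 2 higher and 3 lower of 8 (0.98, Tnfrsf11b -1.09 ± 0.13) and immediate early genes 4 higher and 5 lower of 20 (0.97, Fosl1 -1.64 ± 0.29). Notch pathway genes were 1 higher and 3 lower of 10 (0.35, Jag2 -2.77 ± 0.26) and cholesterol biosynthesis genes 5 higher and 3 lower of 18 (0.43, Dhcr7 1.04 ± 0.13). Among markers of other cell types, adipocyte markers were 1 higher and 2 lower of 7 (0.3), skeletal muscle markers 1 higher and 0 lower of 6 (0.48), blood cell markers 0 higher and 0 lower of 7 (0.97), endothelial markers 0 higher and 0 lower of 6 (0.43) and fibroblast and tendon markers 2 higher and 1 lower of 8 (0.83). The adipogenic receptor Pparg was 64-fold (95% interval 17.4 to 533) lower and Cd34 72.7-fold (95% interval 19.8 to 605) lower in KO, and Ptprc, a pan-leukocyte gene, was not called (0.31, adjusted p = 0.508).

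At day 14 the lines were farthest apart, with 6842 genes called, 3280 higher and 3562 lower in KO, of which 458 and 1285 changed more than 2-fold. The endoplasmic reticulum genes Hspa5 (-2.28 ± 0.07, adjusted p = 5.74e-16) and Sdf2l1 (-3.09 ± 0.09, adjusted p = 5.65e-16) were far lower in KO. Col1a1 was higher in KO (1.31 ± 0.16, adjusted p = 6.55e-07).

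The highest log2 fold changes at day 14 were again those of homeobox and zinc finger genes. Hoxd4 was 98.6-fold (95% interval 17.3 to 3930) higher, Zic2 was at 5.54 ± 0.34, adjusted p = 3.2e-11, Hoxb8 at 4.42 ± 0.41, Hoxd8 at 4.35 ± 0.32, Hoxb9 at 4.25 ± 0.20 and Hoxb5 at 3.89 ± 0.53. Dapk1 (3.67 ± 0.25) and the carbonic anhydrase Car3 (3.37 ± 0.11, adjusted p = 1.48e-15) followed. The laminin chain Lama2 was at least 172-fold lower, Ccdc149 at least 104-fold, Gsg1l at least 42.3-fold, Tmod2 at least 29-fold, Acot6 at least 25-fold and the bone-secreted peptide gene Ostn at least 29-fold. Ildr2 was 444-fold (95% interval 123 to 3670) lower, and the transcription factor Klf15 was at -7.89 ± 0.29, adjusted p = 7.77e-15.

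All 17 unfolded protein and integrated stress response genes were lower in KO at day 14 (0 higher, 0 not called), with a median of -1.76 (adjusted p = 1.8e-38, adjusted p = 0.00025 with an estimated correlation). Hspa5 (ENSMUSG00000026864.13, chromosome 2, 34771970 to 34777547) averaged 5125 ± 195 CPM in WT and 1056 ± 34.2 CPM in KO (SD, n = 2). Ddit3 (-2.67 ± 0.09, adjusted p = 1.31e-15), Trib3 (-2.69 ± 0.08) and Hyou1 (-2.14 ± 0.09) were also among the lowest. It was the only list at day 14 whose call held with an estimated correlation. Interferon-stimulated genes were 0 higher, 15 lower and 2 not called, with a median of -1.69 (adjusted p = 1.3e-09, adjusted p = 0.22 with an estimated correlation), as in Oasl2 (-2.78 ± 0.13, adjusted p = 5.64e-13), Isg15 (-2.45 ± 0.19) and the transcription factor Irf9 (-1.69 ± 0.11). Glycolysis and hypoxia genes remained lower (0 higher and 14 lower of 19, median -0.76, adjusted p = 0.00027, adjusted p = 0.61 with an estimated correlation). Slc2a1 was at -1.44 ± 0.09 and Hk2 at -0.80 ± 0.10. YAP/TAZ target genes were lower (3 higher and 12 lower of 22, 4 and 12 adjusted over the list alone, median -0.58, adjusted p = 0.0026, adjusted p = 0.12 with an estimated correlation), through Ankrd1 (-2.54 ± 0.19, adjusted p = 4.26e-10), the ectonucleotidase Nt5e (-1.87 ± 0.11) and Amotl2 (-1.36 ± 0.08).

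Of the 18 osteoblast and bone matrix genes at day 14, 13 were higher, 4 lower and 1 not called, with a median of 0.64 (adjusted p = 0.0034, adjusted p = 0.76 with an estimated correlation). The osteogenic transcription factors Runx2 (0.92 ± 0.10, adjusted p = 8.71e-08) and Sp7 (1.06 ± 0.16, adjusted p = 9.11e-06) and the mineralization gene Ifitm5 (1.31 ± 0.15) were higher. Spp1 (-0.81 ± 0.09), Ibsp (-0.56 ± 0.13) and Bglap2 (-1.06 ± 0.14), which encode mineral-associated proteins, were lower. Cell cycle genes were higher (20 higher and 1 lower of 24, median 0.44, adjusted p = 1e-06, adjusted p = 0.12 with an estimated correlation). Plk1 was at 1.24 ± 0.09 and Mki67 at 0.77 ± 0.06. Mitochondrially encoded genes were higher as well (7 higher and 0 lower of 12, median 0.65, adjusted p = 0.011, adjusted p = 0.61 with an estimated correlation). The complex I gene mt-Nd1 was at 0.92 ± 0.10. Osteocyte markers were not called (2 higher and 6 lower of 13, median -0.39, adjusted p = 0.085), although Dmp1 (-0.92 ± 0.23, adjusted p = 0.00185), Ackr3 (-4.66 ± 0.48) and Fam20c (-0.57 ± 0.10) were lower. Among lists that were not called, the connexin 43 gene Gja1 was higher (1.49 ± 0.09, adjusted p = 2.07e-11) and Piezo2 lower (-2.81 ± 0.15). The Wnt regulators Wif1 (2.23 ± 0.17), Sfrp1 (3 ± 0.14) and Wnt4 (1.36 ± 0.13) were higher against Sfrp2 (-1.42 ± 0.11). Inhba (-2.54 ± 0.10) and Grem1 (-2.43 ± 0.29) of the BMP and TGF-beta list were lower.

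At day 28 5646 genes differed, 2730 higher and 2916 lower in KO, with 192 and 1074 changed more than 2-fold. All 17 interferon-stimulated genes tested were lower in KO, a list call that was lost with an estimated correlation (adjusted p = 0.069). The stress response gene Creld2 was higher (0.96 ± 0.06, adjusted p = 1.98e-10). Runx2 (0.01, adjusted p = 0.924) was not called, while Bmp2 was higher (2.17 ± 0.06, adjusted p = 1.64e-15). Col1a1 was not called (-0.17, adjusted p = 0.396), but passed at -0.43 without WT day 28 replicate 2 and at -0.58 without KO day 28 replicate 1. With library totals only, 1809 genes were higher and 3692 lower of 5501 called, so here too the balance depends on the scaling. Fitting only the day 28 libraries called 3721 genes.

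At day 28 Hoxd4 was 59.4-fold (95% interval 10.2 to 2380) higher, and Zic2 (ENSMUSG00000061524.8, chromosome 14, 122475435 to 122479852) was at 4.58 ± 0.42, adjusted p = 2.42e-08, Hoxb9 at 4.34 ± 0.15, Hoxd8 at 4.01 ± 0.27, Hoxb8 at 3.83 ± 0.44, Dapk1 at 3.82 ± 0.18, Lrp3 at 3.32 ± 0.26 and the microtubule protein gene Mapt at 3.08 ± 0.26. The potassium channel gene Kcns3 was at least 35.5-fold lower, Adgrg2 238-fold (95% interval 42.2 to 9420), Aplp1 168-fold (95% interval 29.7 to 6670) and Alx1 131-fold (95% interval 35.8 to 1090). The peroxidase gene Gpx7 (ENSMUSG00000028597.11, chromosome 4, 108400390 to 108406961) was 163-fold (95% interval 55.3 to 792) lower. Lgi2 (-7.29 ± 0.23, adjusted p = 3.39e-15), Ildr2 (-7.03 ± 0.25) and Armcx4 (-7.01 ± 0.27) were also among the lowest.

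All 17 interferon-stimulated genes tested were lower at day 28 (0 higher, 0 not called), with a median of -1.82 (adjusted p = 3.3e-22, adjusted p = 0.069 with an estimated correlation). Oasl2 was at -2.30 ± 0.10, adjusted p = 6.69e-13, Isg15 at -2.21 ± 0.16 and the RNA sensor gene Ddx58 at -1.55 ± 0.09. Glycolysis and hypoxia genes were 0 higher, 17 lower and 2 not called, with a median of -0.89 (adjusted p = 4e-09, adjusted p = 0.46 with an estimated correlation), including Pdk1 (-1.92 ± 0.17), Aldoa (-1.51 ± 0.15) and Egln3 (-2.60 ± 0.30). Collagen processing and cross-linking genes were lower (2 higher and 11 lower of 16, 2 and 12 adjusted over the list alone, median -0.55, adjusted p = 3e-04, adjusted p = 0.51 with an estimated correlation). Loxl2 was at -1.39 ± 0.12 and P4ha1 at -1.26 ± 0.13. Dendrite and axon guidance genes were lower (3 higher and 13 lower of 21, median -0.34, adjusted p = 4e-04, adjusted p = 0.46 with an estimated correlation), as in Sema3d (-2.53 ± 0.14), Sema3c (-2.36 ± 0.16) and Unc5c (-1.91 ± 0.18), with Efnb2 (0.57 ± 0.08) the other way. Immediate early genes were lower (1 higher and 10 lower of 20, median -0.53, adjusted p = 0.011, adjusted p = 0.63 with an estimated correlation). Jun was at -1.21 ± 0.10 and Egr1 at -0.83 ± 0.12. No list call at day 28 held with an estimated correlation.

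Cell cycle genes were higher at day 28 (15 higher and 0 lower of 24, 16 and 0 adjusted over the list alone, median 0.26, adjusted p = 0.00039, adjusted p = 0.4 with an estimated correlation), as in Mcm3 (0.73 ± 0.06, adjusted p = 1.01e-08) on chromosome 1 and Mcm5 (0.62 ± 0.06). Unfolded protein and integrated stress response genes were called higher (7 higher and 3 lower of 17, 7 and 4 adjusted over the list alone, median 0.11, adjusted p = 0.023, adjusted p = 0.39 with an estimated correlation), with Pdia4 (0.85 ± 0.07) and Phgdh (0.64 ± 0.07) higher and Dnajb9, chosen after its values were seen, lower (-0.44 ± 0.10). Cholesterol biosynthesis genes were lower (0 higher and 10 lower of 18, median -0.27, adjusted p = 0.0064, adjusted p = 0.63 with an estimated correlation). Insig1 was at -0.68 ± 0.07 and Lss at -0.62 ± 0.08. Chondrocyte markers were lower (0 higher and 5 lower of 10, median -0.67, adjusted p = 0.0087, adjusted p = 0.51 with an estimated correlation). Hapln1 was at -2.27 ± 0.19 and Sox9 at -0.67 ± 0.09. Neither osteocyte markers (1 higher and 5 lower of 13, adjusted p = 0.48, Ackr3 -3.03 ± 0.55) nor osteoblast genes (4 higher and 5 lower of 18, adjusted p = 0.69) were called. Within the latter Postn was higher (1.35 ± 0.10) and Alpl (-1.23 ± 0.15) and Spp1 (-1.26 ± 0.08) were lower.

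A part of the difference between the lines was present on every day. In the 3 comparisons, which share no libraries, 1019 genes were higher in KO on all 3 days against 127 expected of independent lists, and 1194 were lower against 157 expected. With chromosome medians subtracted, an alternative chosen after seeing the data, 581 genes were higher and 886 lower on all 3 days, 458 and 796 of them among those above. More than 2-fold on each day were 78 genes higher and 517 lower. Calls in opposite directions on different days were made for 791 genes, and 4115 were called on no day. The highest genes by their smallest change over the days were Hoxd4, Hoxd8, Zic2, Dapk1, Hoxb8 (3.25, 4.42 and 3.83 at days 1, 14 and 28), Hoxb5 (3.21, 3.89 and 2.98), the teneurin gene Tenm3 (3.49, 3.05 and 2.82) and Mapt. Among the lowest, Gpx7 was 368-fold (95% interval 65.7 to 14600) lower at day 1 and 245-fold (95% interval 67.5 to 2030) lower at day 14. Armcx4 was at -6.84, -7.76 and -7.01, and the amino acid transporter gene Slc6a15 was 282-fold (95% interval 96.2 to 1370) lower at day 1 and at -6.98 and -6.62 on the later days. Kif1a, a neuronal kinesin gene, was at least 14.6-fold lower at day 1 and at -6.15 at day 28. Ildr2, Alx1, Aplp1 and Ccdc149 were the others.

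**Figure D3:**
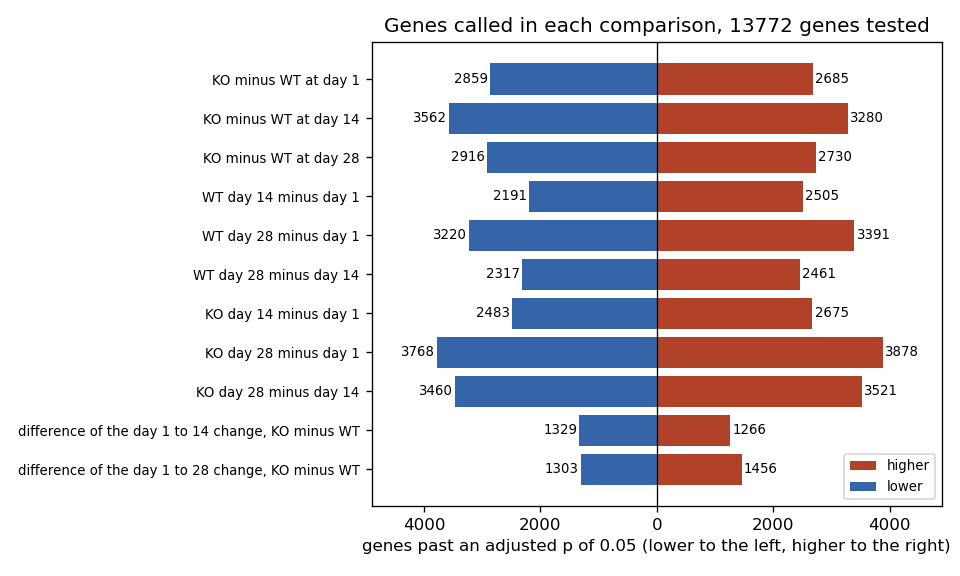
Number of genes called at an adjusted p below 0.05 in each of the 11 comparisons, with bars to the right for higher and to the left for lower genes. KO minus WT gives 5544, 6842 and 5646 genes at days 1, 14 and 28, and the differences of change between the lines give 2595 and 2759.

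**Figure D4:**
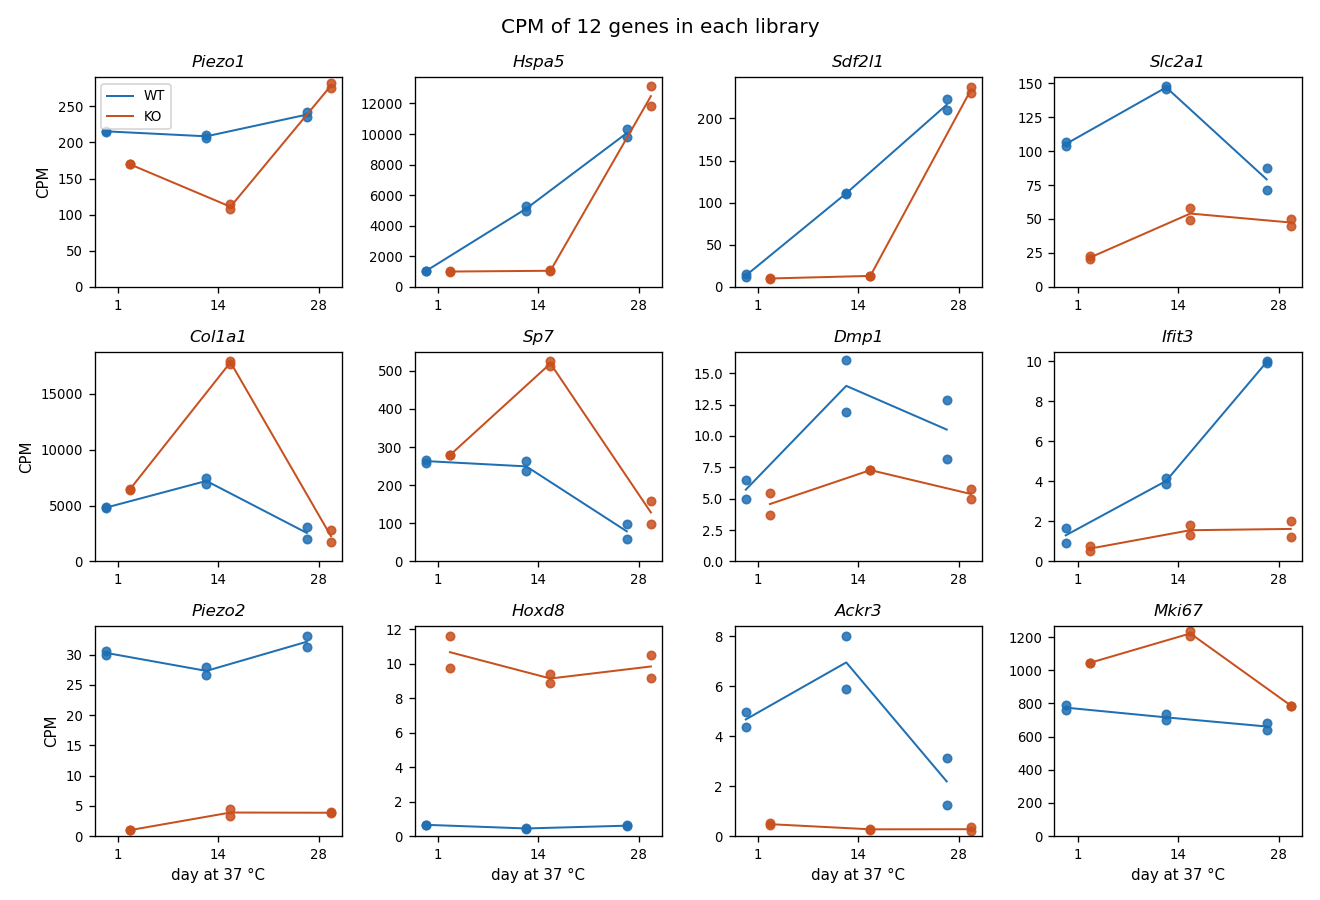
CPM of 12 genes by day, with 1 point per library, lines joining the group means, WT in blue and KO in orange. At day 14 Hspa5 averages 5125 CPM in WT and 1056 CPM in KO, and at day 28 10060 and 12480 CPM.

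From day 1 to day 14 in WT, 2505 genes rose and 2191 fell, 611 and 214 of them more than 2-fold. The chaperone gene Hspa5 rose by 2.31 ± 0.07, adjusted p = 5.24e-16, Dmp1, which encodes a matrix protein of early osteocytes, by 1.27 ± 0.22, adjusted p = 0.000146 and Bglap2, an osteocalcin gene, by 2.56 ± 0.16, adjusted p = 9.45e-11. Without WT day 1 replicate 2 the number of calls dropped from 4696 to 3113. With library totals only, 2063 genes were higher and 2958 lower of 5021 called.

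Of the 17 unfolded protein and integrated stress response genes, 11 were higher, 4 lower and 2 not called (12 and 5 adjusted over the list alone) in WT at day 14, with a median of 0.48 (adjusted p = 2.6e-26, adjusted p = 0.00063 with an estimated correlation), and Sdf2l1 was at 3.04 ± 0.09, adjusted p = 2.82e-16. Only this list held with an estimated correlation. Interferon-stimulated genes were 15 higher, 0 lower and 2 not called, with a median of 1.61 (adjusted p = 5.6e-22, adjusted p = 0.077 with an estimated correlation). Oasl2 was at 2.53 ± 0.12 and Irf9 at 1.25 ± 0.10. Osteocyte markers, including the stress response gene Hyou1, rose (5 higher and 0 lower of 13, median 0.23, adjusted p = 0.013, adjusted p = 0.6 with an estimated correlation). Osteoblast genes did too (11 higher and 1 lower of 18, 11 and 2 adjusted over the list alone, median 0.42, adjusted p = 0.013, adjusted p = 0.65 with an estimated correlation). Col1a2 was at 0.69 ± 0.11 and Postn at 0.67 ± 0.10. Dendrite and axon guidance genes rose (11 higher and 0 lower of 21, 12 and 1 adjusted over the list alone, median 0.45, adjusted p = 0.00027, adjusted p = 0.5 with an estimated correlation), with the axon repellent gene Slit2 at 0.87 ± 0.08 and the netrin receptor gene Unc5c at 1.77 ± 0.19. Cholesterol biosynthesis genes fell (0 higher and 13 lower of 18, median -0.50, adjusted p = 1.1e-07, adjusted p = 0.5 with an estimated correlation). Hmgcs1 was at -0.80 ± 0.09.

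From day 1 to day 28 in WT, 3391 genes rose and 3220 fell, 921 and 531 of them more than 2-fold (2936 rose and 3785 fell with library totals only). The highest were the interferon-inducible GTPase genes Gbp6 (7.49 ± 0.40, adjusted p = 4.54e-12) and Gbp9 (5.91 ± 0.39), Ostn (5.11 ± 0.30, adjusted p = 8.8e-11), Slfn8 (4.81 ± 0.19), Abca8a (4.77 ± 0.19), Ifi44 (4.61 ± 0.25), the class I gene H2-Q6 (4.53 ± 0.27) and Rtp4 (4.45 ± 0.26). Among the lowest were Ankrd37 (-3.58 ± 0.23, adjusted p = 6.04e-11), B4galnt4 (-3.43 ± 0.31), Peg12 (-3.30 ± 0.30), Abi3 (-3.02), Spock2 (-3.01), Smtnl2 (-2.80) and Anxa8 (-2.71). Unfolded protein and integrated stress response genes rose further (15 higher and 0 lower of 17, median 1.36, adjusted p = 6.7e-52, adjusted p = 8.4e-05 with an estimated correlation). Creld2 was at 3.64 ± 0.07, adjusted p = 3.66e-19 and Hspa5 at 3.28 ± 0.07. Interferon-stimulated genes did too (16 higher and 0 lower of 17, median 2.13, adjusted p = 3.6e-31, adjusted p = 0.035 with an estimated correlation), and both calls held with an estimated correlation.

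Osteoblast and bone matrix genes were lower in WT at day 28 than at day 1 (3 higher and 13 lower of 18, median -0.83, adjusted p = 0.0012, adjusted p = 0.74 with an estimated correlation). The mineralization genes Phospho1 (-2.12 ± 0.11, adjusted p = 5.71e-12) and Smpd3 (-2.45 ± 0.21) and Sp7 (-1.73 ± 0.17) fell, against rises of Spp1 (1.53 ± 0.08) and Bglap2 (2.64 ± 0.15). Osteocyte markers were not called (4 higher and 3 lower of 13, adjusted p = 0.46). Actin and focal adhesion genes fell (1 higher and 11 lower of 20, 1 and 12 adjusted over the list alone, median -0.30, adjusted p = 0.0028, adjusted p = 0.74 with an estimated correlation). Tpm1 was at -1.22 ± 0.07. The glycolysis and hypoxia list fell (2 higher and 14 lower of 19, 3 and 14 adjusted over the list alone, median -0.70, adjusted p = 1e-04, adjusted p = 0.74 with an estimated correlation). Ldha was at -1.06 ± 0.13. Wnt/beta-catenin target genes fell (2 higher and 7 lower of 13, median -0.90, adjusted p = 0.049, adjusted p = 0.74 with an estimated correlation). Lef1 was at -1.84 ± 0.17. Dendrite and axon guidance genes were called higher (9 higher and 3 lower of 21, 9 and 4 adjusted over the list alone, median 0.05, adjusted p = 0.004, adjusted p = 0.74 with an estimated correlation). Slit2 was at 2.13 ± 0.07.

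Between days 14 and 28 in WT, 2461 genes rose and 2317 fell, 301 and 317 of them more than 2-fold. Osteoblast and bone matrix genes fell (1 higher and 16 lower of 18, median -1.18, adjusted p = 2.2e-16, adjusted p = 0.29 with an estimated correlation). Postn was at -1.66 ± 0.10, adjusted p = 3.2e-10 and Col1a2 at -1.09 ± 0.11. Unfolded protein and integrated stress response genes rose (16 higher and 0 lower of 17, 16 and 1 adjusted over the list alone, median 0.89, adjusted p = 4.5e-26, adjusted p = 0.00065 with an estimated correlation), with Hspa5 at 0.97 ± 0.07, and were the only list to hold with an estimated correlation. Glycolysis and hypoxia genes fell (0 higher and 15 lower of 19, 0 and 16 adjusted over the list alone, median -0.89, adjusted p = 1.5e-13, adjusted p = 0.29 with an estimated correlation). Slc2a1 was at -0.89 ± 0.09. Collagen processing and cross-linking genes fell as well (0 higher and 11 lower of 16, median -0.38, adjusted p = 7.2e-07, adjusted p = 0.32 with an estimated correlation). Loxl4 was at -1.10 ± 0.08. So did actin and focal adhesion genes (2 higher and 9 lower of 20, 2 and 11 adjusted over the list alone, median -0.17, adjusted p = 2.8e-08, adjusted p = 0.32 with an estimated correlation). Acta2 was at -1.45 ± 0.07. Chondrocyte markers were lower (1 higher and 6 lower of 10, 1 and 7 adjusted over the list alone, median -1, adjusted p = 0.0023, adjusted p = 0.32 with an estimated correlation). The hedgehog ligand gene Ihh was at -3.24 ± 0.41. Wnt/beta-catenin target genes fell (1 higher and 7 lower of 13, median -0.46, adjusted p = 0.017, adjusted p = 0.46 with an estimated correlation). The feedback inhibitor Axin2 was at -1.03 ± 0.15. Secreted Wnt ligands and inhibitors were lower too (2 higher and 6 lower of 14, median -0.27, adjusted p = 0.022, adjusted p = 0.49 with an estimated correlation). Sfrp2 was at -1.11 ± 0.11.

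Interferon-stimulated genes rose further in WT from day 14 to day 28 (13 higher and 0 lower of 17, median 0.76, adjusted p = 4.5e-09, adjusted p = 0.29 with an estimated correlation). Oasl2 was at 0.96 ± 0.10. Cholesterol biosynthesis genes rose (11 higher and 0 lower of 18, median 0.46, adjusted p = 2.9e-06, adjusted p = 0.35 with an estimated correlation). Insig1 was at 1.19 ± 0.07. Mitochondrially encoded genes rose (5 higher and 0 lower of 12, 6 and 0 adjusted over the list alone, median 0.51, adjusted p = 0.0058, adjusted p = 0.48 with an estimated correlation). Immediate early genes were called higher (5 higher and 5 lower of 20, 6 and 5 adjusted over the list alone, median 0.22, adjusted p = 0.022, adjusted p = 0.57 with an estimated correlation). Egr1 was at 1.41 ± 0.12.

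In the KO line 2675 genes rose and 2483 fell from day 1 to day 14, 577 and 438 of them more than 2-fold (2247 rose and 2927 fell with library totals only). The unfolded protein and integrated stress response list was not called (6 higher and 7 lower of 17, median 0.02, adjusted p = 0.22), and its change differed from that in WT (adjusted p = 2.8e-34). Trib3 (-1.33 ± 0.09) and Ddit3 (-1.11 ± 0.09) fell. Osteoblast and bone matrix genes were 15 higher, 0 lower and 3 not called, with a median of 0.88 (adjusted p = 5.5e-14, adjusted p = 0.18 with an estimated correlation), including Col1a1 (1.46 ± 0.16, adjusted p = 3.26e-07) and Postn (1.37 ± 0.10). Collagen processing and cross-linking genes rose (12 higher and 1 lower of 16, 14 and 1 adjusted over the list alone, median 0.54, adjusted p = 6.2e-19, adjusted p = 0.12 with an estimated correlation). Loxl2 was at 2.22 ± 0.12 and Plod2 at 1.44 ± 0.07. Glycolysis and hypoxia genes rose (17 higher and 0 lower of 19, median 0.95, adjusted p = 4.3e-16, adjusted p = 0.15 with an estimated correlation), with Slc2a1 (ENSMUSG00000028645.11, chromosome 4, 119108711 to 119137983, overlapped by Gm12868 on the opposite strand) at 1.33 ± 0.11. No list of this comparison held with an estimated correlation.

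Cell cycle genes rose in KO by day 14 (18 higher and 0 lower of 24, 21 and 0 adjusted over the list alone, median 0.29, adjusted p = 8.9e-06, adjusted p = 0.14 with an estimated correlation). The p53 target genes fell (0 higher and 9 lower of 19, median -0.27, adjusted p = 0.0041, adjusted p = 0.12 with an estimated correlation). Trp53inp1 was at -0.83 ± 0.08. YAP/TAZ target genes fell (2 higher and 14 lower of 22, median -0.38, adjusted p = 3.2e-05, adjusted p = 0.072 with an estimated correlation). Nt5e was at -1.72 ± 0.11 and Ccn2 at -1.48 ± 0.18. Notch pathway genes rose (6 higher and 1 lower of 10, median 0.78, adjusted p = 0.0071, adjusted p = 0.15 with an estimated correlation). Hey1 was at 3.19 ± 0.19. Dendrite and axon guidance genes rose (10 higher and 5 lower of 21, 11 and 5 adjusted over the list alone, median 0.56, adjusted p = 6.3e-05, adjusted p = 0.18 with an estimated correlation). Cholesterol biosynthesis genes fell (0 higher and 16 lower of 18, median -0.63, adjusted p = 1.3e-10, adjusted p = 0.17 with an estimated correlation). Cyp51 was at -0.85 ± 0.08. Chondrocyte markers were called higher (4 higher and 2 lower of 10, adjusted p = 0.0033, adjusted p = 0.23 with an estimated correlation) on a positive mean of 0.48 and a negative median of -0.26, carried by Col11a2 (2.92 ± 0.17) and Col11a1 (1.93 ± 0.09). Osteocyte markers were not called (2 higher and 5 lower of 13, adjusted p = 0.37).

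From day 1 to day 28 in KO, 3878 genes rose and 3768 fell, 1051 and 1013 of them more than 2-fold (3207 rose and 4483 fell with library totals only). Ostn was at least 45.2-fold higher, Gbp9 176-fold (95% interval 48.3 to 1460), Mlip 78-fold (95% interval 21.2 to 649), Dpyd 59.7-fold (95% interval 16.2 to 498), Map2 64.5-fold (95% interval 11.2 to 2580) and Enpep at least 4.81-fold, with Tfcp2l1 at 6.04 ± 0.33 and Gbp6 at 5.65 ± 0.44. The epithelial transcription factor Grhl3 (-5.26 ± 0.22, adjusted p = 6.45e-14), the plakophilin gene Pkp2 (-4.60 ± 0.40), Anxa8 (-4.56 ± 0.30), Zfp462 (-4.35 ± 0.23), Txnip (-3.92 ± 0.12, adjusted p = 9.91e-17), and the matrix genes Omd (-3.87 ± 0.22) and Mgp (-3.73 ± 0.22) fell most, and Adamts18 was 18-fold (95% interval 5.83 to 90.2) lower. All 17 unfolded protein and integrated stress response genes rose (0 lower, 0 not called), with a median of 2.34 (adjusted p = 2.2e-70, adjusted p = 3.4e-05 with an estimated correlation), the only list to hold with an estimated correlation. Hspa5 rose by 3.63 ± 0.07, adjusted p = 2.31e-19 and Sdf2l1 by 4.54 ± 0.09. Interferon-stimulated genes rose (12 higher and 0 lower of 17, median 1, adjusted p = 0.0012, adjusted p = 0.76 with an estimated correlation). Oasl2 was at 2.60 ± 0.16. Actin and focal adhesion genes fell (1 higher and 16 lower of 20, 1 and 17 adjusted over the list alone, median -0.70, adjusted p = 2.2e-07, adjusted p = 0.76 with an estimated correlation). Tpm1 was at -1.66 ± 0.07. Genes of osteoblasts and bone matrix fell (3 higher and 11 lower of 18, median -0.76, adjusted p = 0.014, adjusted p = 0.89 with an estimated correlation). Smpd3 was at -3.14 ± 0.22. Wnt/beta-catenin target genes were lower (2 higher and 8 lower of 13, median -1.20, adjusted p = 0.017, adjusted p = 0.76 with an estimated correlation). Apcdd1 was at -2.87 ± 0.13. Cholesterol biosynthesis genes fell in KO by day 28 (1 higher and 12 lower of 18, median -0.63, adjusted p = 0.0012, adjusted p = 0.76 with an estimated correlation). Hmgcs1 was at -1.22 ± 0.09.

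In KO more genes changed between days 14 and 28 than between days 1 and 14: 3521 genes rose and 3460 fell, 858 and 852 of them more than 2-fold (3161 rose and 3785 fell with library totals only). All 17 unfolded protein and integrated stress response genes rose, with 0 lower and a median of 2.5 (adjusted p = 6.2e-82, adjusted p = 2.1e-05 with an estimated correlation), and this call alone held with an estimated correlation. Hspa5 was at 3.56 ± 0.07, adjusted p = 4.29e-19 and Trib3 at 3.71 ± 0.08. The osteoblast and bone matrix list fell (2 higher and 15 lower of 18, median -1.71, adjusted p = 1.3e-15, adjusted p = 0.33 with an estimated correlation). Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) was at -2.98 ± 0.17, adjusted p = 4.78e-12 and Col1a2 at -1.96 ± 0.11. Collagen processing and cross-linking genes fell (0 higher and 15 lower of 16, 0 and 16 adjusted over the list alone, median -1.03, adjusted p = 1e-12, adjusted p = 0.3 with an estimated correlation). Loxl2 was at -1.89 ± 0.12. The glycolysis and hypoxia list did the same (3 higher and 13 lower of 19, median -1.31, adjusted p = 5.3e-07, adjusted p = 0.47 with an estimated correlation). Aldoa was at -2.13 ± 0.15. Actin and focal adhesion genes fell (1 higher and 14 lower of 20, median -0.39, adjusted p = 2.3e-05, adjusted p = 0.49 with an estimated correlation). Tpm1 was at -1.61 ± 0.07.

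Cell cycle genes fell in KO from day 14 to day 28 (2 higher and 16 lower of 24, 4 and 16 adjusted over the list alone, median -0.32, adjusted p = 0.0063, adjusted p = 0.43 with an estimated correlation). Mki67 was at -0.63 ± 0.06. Chondrocyte markers were lower (0 higher and 4 lower of 10, median -0.44, adjusted p = 0.005, adjusted p = 0.43 with an estimated correlation). Col11a1 was at -2.63 ± 0.09. Wnt/beta-catenin target genes fell (3 higher and 8 lower of 13, median -1.27, adjusted p = 0.0063, adjusted p = 0.47 with an estimated correlation). Axin2 was at -2.08 ± 0.15. Secreted Wnt ligands and inhibitors were lower (1 higher and 6 lower of 14, median -0.27, adjusted p = 0.045, adjusted p = 0.6 with an estimated correlation). Wif1 was at -1.95 ± 0.16. YAP/TAZ target genes rose (12 higher and 1 lower of 22, median 0.32, adjusted p = 0.0093, adjusted p = 0.24 with an estimated correlation). Amotl2 was at 1.45 ± 0.08. Interferon-stimulated genes rose (10 higher and 1 lower of 17, median 0.47, adjusted p = 0.043, adjusted p = 0.67 with an estimated correlation). Ifi44 was at 2.66 ± 0.33.

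The changes of the lines were related across genes, which are not independent replicates. Over 13772 genes the WT and KO changes from day 1 to day 28, which share no library, had a Pearson r of 0.674 and a Spearman rho of 0.69. Of 4800 genes called in both lines, 4576 changed in the same direction and 224 in opposite directions. From day 1 to day 14 r was 0.465 and rho 0.454, with 2189 of 2483 genes in the same direction. From day 14 to day 28 r was 0.496 and rho 0.527, with 3078 of 3360 in the same direction.

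The difference between the lines in their change from day 1 to day 14 was tested directly and called 2595 genes, 1266 with a higher and 1329 with a lower change in KO (1357 and 1244 with library totals only). Hspa5 differed by -2.23 ± 0.10, adjusted p = 1.12e-12 and Creld2 by -2.25 ± 0.10, and Runx2 differed by 0.90 ± 0.13, adjusted p = 6.11e-05 in the other direction. Leaving out KO day 1 replicate 2 left 1678 calls, and leaving out KO day 14 replicate 1 left 1679. The unfolded protein and integrated stress response list had a lower change in KO (0 higher and 12 lower of 17, median -0.78, adjusted p = 2.8e-34, adjusted p = 0.00029 with an estimated correlation). YAP/TAZ target genes did too (0 higher and 11 lower of 22, 1 and 11 adjusted over the list alone, median -0.40, adjusted p = 8.5e-06, adjusted p = 0.027 with an estimated correlation). Nt5e was at -1.40 ± 0.14 and Axl at -0.89 ± 0.10. These calls alone held with an estimated correlation.

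Osteocyte markers had a lower change in KO at day 14 (0 higher and 5 lower of 13, median -0.55, adjusted p = 7.4e-05, adjusted p = 0.17 with an estimated correlation), with Phex at -1.40 ± 0.32, adjusted p = 0.00342 and Hyou1, also a stress response gene, at -1.76 ± 0.13. The osteoblast and bone matrix list had a higher one (13 higher and 2 lower of 18, 13 and 3 adjusted over the list alone, median 0.82, adjusted p = 6.3e-07, adjusted p = 0.38 with an estimated correlation). Dlx5 was at 0.96 ± 0.15, adjusted p = 8.76e-05 and Bglap2 went the other way (-2.10 ± 0.23). Collagen processing and cross-linking genes had a higher change (13 higher and 0 lower of 16, median 0.63, adjusted p = 1.6e-14, adjusted p = 0.15 with an estimated correlation). Loxl2 was at 1.78 ± 0.16 and Plod2 at 1.09 ± 0.10. The glycolysis and hypoxia list had a higher one too (16 higher and 0 lower of 19, 16 and 1 adjusted over the list alone, median 0.92, adjusted p = 1.5e-14, adjusted p = 0.17 with an estimated correlation). Vegfa was at 0.82 ± 0.09. Cell cycle genes had a higher change (8 higher and 0 lower of 24, 9 and 1 adjusted over the list alone, median 0.19, adjusted p = 0.0078, adjusted p = 0.31 with an estimated correlation). Chondrocyte markers were called higher (3 higher and 0 lower of 10, 4 and 0 adjusted over the list alone, median 0.46, adjusted p = 0.013, adjusted p = 0.32 with an estimated correlation). Interferon-stimulated genes had a lower change in KO (0 higher and 9 lower of 17, 1 and 10 adjusted over the list alone, median -1.15, adjusted p = 2.7e-08, adjusted p = 0.18 with an estimated correlation). Irf7 was at -2.42 ± 0.33. Actin and focal adhesion genes were called lower (1 higher and 6 lower of 20, median -0.16, adjusted p = 0.027, adjusted p = 0.67 with an estimated correlation). Tagln was at -1.42 ± 0.23. The p53 target genes had a lower change (0 higher and 3 lower of 19, 0 and 5 adjusted over the list alone, median -0.35, adjusted p = 0.0094, adjusted p = 0.15 with an estimated correlation).

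For the change from day 1 to day 28, 2759 genes differed between the lines, 1456 with a higher and 1303 with a lower change in KO (1225 and 1440 with library totals only). Trib3 of the stress response list was at 1.67 ± 0.09, adjusted p = 1.36e-10. The number of calls was 1703 without KO day 1 replicate 2, 1810 without KO day 1 replicate 1 and 3919 without WT day 28 replicate 2. Of the 17 stress response genes, 15 were higher, 0 lower and 2 not called, with a median of 0.67 (adjusted p = 6.3e-18, adjusted p = 0.0019 with an estimated correlation), the only list to hold with an estimated correlation. Glycolysis and hypoxia genes had a higher change (7 higher and 0 lower of 19, median 0.60, adjusted p = 6.3e-07, adjusted p = 0.46 with an estimated correlation). Slc2a1 was at 1.55 ± 0.14 and Vegfa at 1.26 ± 0.09. Interferon-stimulated genes had a lower change (0 higher and 10 lower of 17, 0 and 14 adjusted over the list alone, median -1.12, adjusted p = 8.3e-11, adjusted p = 0.21 with an estimated correlation). Ddx58 was at -1.41 ± 0.13. Actin and focal adhesion genes, which fell in both lines, had a lower change as well (1 higher and 12 lower of 20, 1 and 13 adjusted over the list alone, median -0.37, adjusted p = 8.3e-05, adjusted p = 0.51 with an estimated correlation).

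Osteocyte markers had a lower change in KO from day 1 to day 28 (1 higher and 5 lower of 13, median -0.39, adjusted p = 0.031, adjusted p = 0.49 with an estimated correlation). Pdpn was at -1.68 ± 0.19. Perilacunar remodelling genes had a lower one too (0 higher and 3 lower of 9, median -0.15, adjusted p = 0.0023, adjusted p = 0.21 with an estimated correlation). Mmp2 was at -1.81 ± 0.11. Immediate early genes were called lower (1 higher and 8 lower of 20, 1 and 9 adjusted over the list alone, median -0.43, adjusted p = 0.0033, adjusted p = 0.51 with an estimated correlation). Jun was at -1.33 ± 0.14. The p53 target genes were called lower (2 higher and 7 lower of 19, 2 and 10 adjusted over the list alone, median -0.24, adjusted p = 0.00039, adjusted p = 0.077 with an estimated correlation). Plk2 was at -1.50 ± 0.16. Cholesterol biosynthesis genes had a lower change (0 higher and 10 lower of 18, 0 and 11 adjusted over the list alone, median -0.46, adjusted p = 1.1e-05, adjusted p = 0.46 with an estimated correlation). Dhcr7 was at -1.02 ± 0.20. Mitochondrially encoded genes were called lower as well (0 higher and 9 lower of 12, 1 and 9 adjusted over the list alone, median -0.81, adjusted p = 3e-05, adjusted p = 0.38 with an estimated correlation). The complex I gene mt-Nd1 was at -0.82 ± 0.14.

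**Figure D5:**
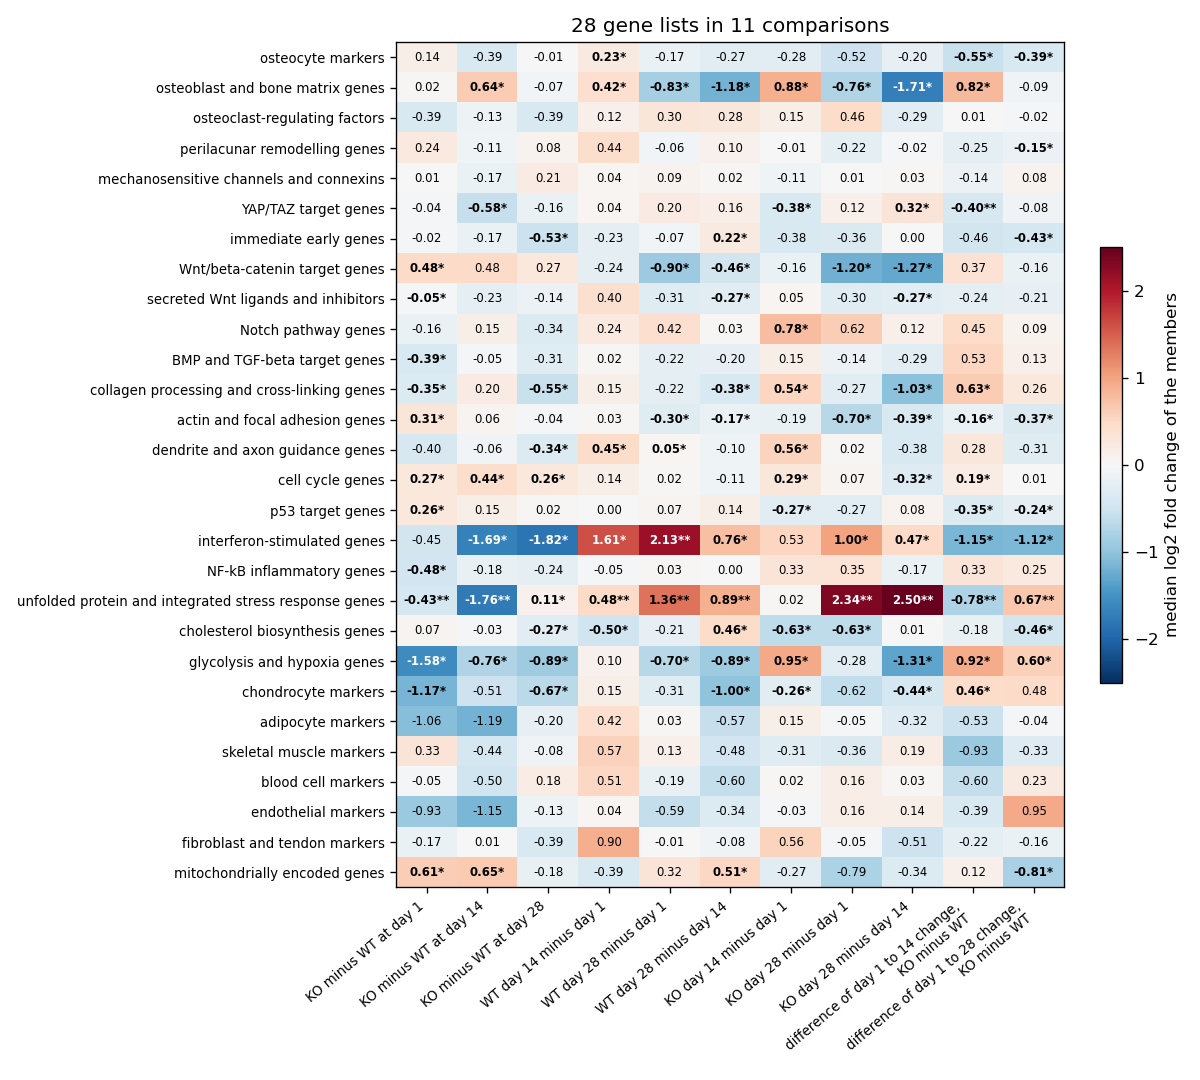
Median log2 fold change of the 28 gene lists (one per line of the heat map) in the 11 comparisons (columns), with a star for lists called with the preset correlation and a double star for those also called with an estimated correlation. The unfolded protein and integrated stress response list has a median of -1.76 in KO minus WT at day 14 and of 2.5 from day 14 to day 28 in KO.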

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

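The tests of chromosome copies, of day 1 cells in the KO day 14 libraries, of Yap1 reads and of a reporter that follows Dmp1 were chosen only after the result was seen.

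The lines differed in how they changed from day 1, by a direct test of the difference with edgeR. At day 14 it called 2595 genes and at day 28 it called 2759. The number was 1678 at day 14 without KO day 1 replicate 2 and 1679 without KO day 14 replicate 1. At day 28 it was 1703 without KO day 1 replicate 2 and 1810 without KO day 1 replicate 1. At day 14 the highest differences of change, KO minus WT, were those of Adamtsl1 (4.49), Mlip (4.40), Gpr35 (4.01), Cd248 (4.01) and the sphingosine phosphate receptor gene S1pr3 (3.97). The lowest were those of the troponin gene Tnni1 (-3.94), the class I gene H2-Q6 (-3.59), Synpo2l (-3.41), the laminin chain Lama3 (-3.41) and Palm3 (-3.28). At day 28 the highest were Bmp8a (4.99), Hapln4 (4.14), the heparanase gene Hpse (3.98), Mark1 (3.93) and Map2 (3.93). The lowest were H2-Q6 (-4.43), Zfp462 (-3.88), Pkp2 (-3.55), Shank1 (-3.15) and Sirpa (-3.14). The call of Bmp8a was lost without WT day 1 replicate 2 (4.75), KO day 1 replicate 1 (5) or 2 (4.98), or KO day 28 replicate 1 (4.84). That of Hapln4 was lost without KO day 28 replicate 2 (3.02, against 7.29 without KO day 1 replicate 2), that of Mark1 without KO day 1 replicate 1 (3.17) or KO day 28 replicate 2 (3.29, against 6.24 without KO day 1 replicate 2) and that of Shank1 without KO day 1 replicate 1 (-2.78). Over the pair of KO day 1 libraries Bmp8a had 0 counts, Mark1 and Map2 1 and Hapln4 and Mlip 2, and Tnni1 had 2 at KO day 14, so the fitted values of these genes depend on the prior count and are no bounds.

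Between days 1 and 14 the change of 11 lists differed between the lines by camera with the preset correlation. Adjusted p was 7.4e-05 for osteocyte markers, 6.3e-07 for osteoblast and bone matrix genes, 8.5e-06 for YAP/TAZ target genes, 1.6e-14 for collagen processing and cross-linking genes, 0.027 for actin and focal adhesion genes and 0.0078 for cell cycle genes. It was 0.0094 for p53 target genes, 2.7e-08 for interferon-stimulated genes, 2.8e-34 for unfolded protein and integrated stress response genes, 1.5e-14 for glycolysis and hypoxia genes and 0.013 for chondrocyte markers. Between days 1 and 28, 10 lists differed. Adjusted p was 0.031 for osteocyte markers, 0.0023 for perilacunar remodelling genes, 0.0033 for immediate early genes, 8.3e-05 for actin and focal adhesion genes and 0.00039 for p53 target genes. For interferon-stimulated genes it was 8.3e-11, for unfolded protein and integrated stress response genes 6.3e-18, for cholesterol biosynthesis genes 1.1e-05, for glycolysis and hypoxia genes 6.3e-07 and for mitochondrially encoded genes 3e-05. With an estimated correlation the day 14 calls of the unfolded protein (adjusted p = 0.00029) and YAP/TAZ lists (0.027) and the day 28 call of the unfolded protein list (0.0019) held.

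The unfolded protein response list was lower in KO in all 17 genes at day 14, at a median of -1.76, against 13 of 17 at day 1 (-0.43) and 3 of 17 at day 28 (0.11). Exchanged genotypes at day 14 were excluded, since 99.2% of 714 genes over 2-fold apart in the same direction at days 1 and 28 kept that direction at day 14. Day 1 cells in place of KO day 14 cells were excluded, since 1012 genes outside the list passed the test with over 2-fold change between KO days 1 and 14. A near-full delay of the whole change was excluded, but not a partial one. The 605 other genes up over 2-fold in WT changed in KO by a median of 60.3% of the WT change. It was 70.5% for the 423 at an average log2 CPM of at least 1. It was 15.4% for the 11 of 17 list genes called higher in WT at any fold, 6 of them called higher in KO too. A delay of this response may be a biological difference, a hypothesis found and tested on the same data with 1 edited line. Culture conditions were not tested.

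Transgene rows outside the comparisons carried reads above the limit that a count of 0 allows. The red fluorescent protein row, Tdtomato, held 17 counts over the libraries of WT day 1, 28 at WT day 14, 3 at WT day 28, and 10, 13 and 8 at KO days 1, 14 and 28. The YAPS127_P2A_EGFP row held 5, 127 and 299 counts at WT days 1, 14 and 28, against 4 and 9 at KO days 14 and 28.

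The YAPS127_P2A_EGFP row held 2 and 3 counts per library at day 1, 82 and 45 at day 14 and 224 and 75 at day 28 in WT. In KO it held 1 and 0, 1 and 3, and 7 and 2. Reads of the endogenous Yap1 gene were excluded as its source, since the ratio of the row to Yap1 differed 32.5-fold between WT and KO at day 28 (18.3-fold to 81.9-fold with 1 library left out). A reporter at a fixed ratio to Dmp1 was excluded, since that ratio differed 37-fold between WT days 28 and 1 (26.5 to 42.6 with 1 library left out). Reads from libraries outside this table and other reporters were not tested. The labels name no such construct, and no biological explanation was tested.

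Whole chromosomes were shifted between the lines on all 3 days, with the median log2 fold change of the 817 chromosome 1 genes at 0.38, 0.41 and 0.40 and of chromosome 5 at -0.30, -0.30 and -0.29. Neither GC content and gene length (chromosome 1 median 0.37 after a fit on both) nor a few strongly changed genes (80.4% of chromosome 1 genes above 0 at day 1, against 47.2% elsewhere) accounted for it. A difference in chromosome copies remains a candidate: the lowest median over 4 segments of chromosome 1 was 0.34. The chromosome moved by 0.11 in KO and 0.08 in WT from day 1 to 28 (difference of change 0.03). Copies and regulation cannot be told apart for these genes, because DNA was not measured.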

How the results depend on the processing

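The removal of chromosome medians, the separation of the camera modes and the other scalings of the gene families were chosen after seeing the data, and the other alternatives were planned. Of 1591 named gene values, 1307 were called, 1139 of them in all alternatives rerun per gene. These were DESeq2 size factors (1590 kept their side of the threshold), Wald test (1524), replicate block (1582) and leaving out 1 library. Over 7508 values with 1 library left out, 7031 kept their side of the threshold (of 1378 uncalled ones among these, 133 changed sign), 410 lost the call, 65 gained it and 2 reversed. Those were the KO minus WT values at day 28 of Dlx3 (0.68, with a lowest value of -0.55 without WT day 28 replicate 2) and of Smpd3 (0, with a lowest of -1.19 without KO day 28 replicate 1), each without WT day 28 replicate 1, and the cause was not tested. Leaving out a library leaves a lone sample that is assumed to vary like the other groups. With fewer libraries WT day 14 minus day 1 gave 3113 to 3404 genes (4696 with all libraries), and the difference of change gave 1678 to 1924 at day 14 (2595) and 1703 to 3919 at day 28 (2759), the highest without WT day 28 replicate 2, for which the cause was not tested. Fitting only the libraries compared gave 7041, 7637 and 3721 genes for KO minus WT at days 1, 14 and 28 (5544, 6842 and 5646). It gave 4093 for the difference of change at day 14 (2595). The spread, widest at day 28, is then not shared (cause untested). The DESeq2 Wald test called fewer in all 11 comparisons, 4562, 5909 and 4594 for KO minus WT by day. Subtracting chromosome medians, which removes shifts of whole chromosomes by construction, gave 1467 genes called on all 3 days in place of 2213. For KO minus WT it gave 4358 genes at day 1, 6275 at day 14 and 4620 at day 28, with 3730, 5495 and 3936 kept in the same direction and 10, 15 and 8 opposite. Lists and named genes were not rerun, so their KO minus WT values keep chromosome shifts. With library totals only, the median over all genes moved by at most 0.089. The share called higher dropped from 48.4% to 38.3% for KO minus WT at day 1, from 48.4% to 32.9% at day 28, and from 53.3% to 41.1% for WT day 14 minus day 1.

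List calls depended most on the mode of camera. Camera with an estimated correlation called 1, 1 and 0 lists in KO minus WT at days 1, 14 and 28, where the preset correlation called 12, 7 and 9. It called 1, 2 and 1 in the WT changes from day 1 to 14, 1 to 28 and 14 to 28 (preset 6, 7 and 12), 0, 1 and 1 in those of KO (10, 6 and 11), and 2 and 1 in the differences of change at days 14 and 28 (11 and 10). This mode changes both the correlation and the degrees of freedom, from those of all genes to the residual ones of the fit. In the same order of comparisons, the estimated correlation alone called 4, 4 and 1 lists for KO minus WT, 2, 2 and 1 for WT, 7, 1 and 2 for KO, and 7 and 4 for the differences of change. The residual degrees of freedom alone called 3, 4 and 5, then 4, 3 and 7, then 7, 2 and 5, and 7 and 7, so each part alone cost calls. Fry, which asks whether a list's own genes move rather than whether they move more than others, called 17, 14 and 16 lists in KO minus WT at days 1, 14 and 28. In the order above it called 11, 15 and 14 for WT, 12, 16 and 17 for KO, and 12 and 9 for the differences of change, the last fewer than the preset mode. With the replicate block 306 of 308 list results kept their side.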

Other observations

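Gene families chosen after their values were seen also parted the lines. Of 81 ribosomal protein genes, 67 rose and 1 fell in WT from day 1 to day 14 (median log2 fold change 0.45), while in KO 12 rose and 8 fell (0.03). KO minus WT was lower for 35 and higher for 4 of them at day 1 (-0.13) and lower for 72 and higher for 3 at day 14 (-0.58), and the difference of change was called for 54, lower in each (-0.44). From day 14 to day 28, 64 rose and 1 fell in KO (0.42), and at day 28 the family was split at 17 higher and 16 lower (0). The change from day 1 to day 28 was higher in KO for 23 and lower for 0. Proteasome genes (symbols in Psm, which include assembly factors and regulators) moved the other way. Of 46, 33 were higher and 5 lower in KO at day 14 (0.55), with 25 higher at day 1 (0.23) and at day 28 (0.20). They fell in WT by day 14 (3 higher, 27 lower) but not in KO (16 higher, 2 lower), and the difference of change was higher for 28 (0.39). With library totals only, chosen for the families after seeing the data, the medians of KO minus WT at day 14 were -0.62 and 0.50. At day 28 they were -0.09 and 0.11, with 10 ribosomal genes higher and 21 lower and 13 proteasome genes higher and 8 lower, so that balance depends on the scaling.

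Of 32 Hox genes tested, which pattern the body axis and are kept stably on or off in cells of one origin, 17, 17 and 15 were higher in KO at days 1, 14 and 28, and 3, 2 and 1 lower. Another 27 genes had at most 3 counts over the 6 KO libraries and over 100 over the WT libraries. Examples are the telomerase gene Tert (2 against 108 counts), the homeobox gene Irx2 (0 against 110), the monoamine oxidase gene Maob (0 against 140), Cyp27a1 (2 against 167), Plek2 (3 against 233), Il12rb2 (3 against 259), Tmod2 (1 against 456) and Alx1 (3 against 656). In the other direction 1 gene met this criterion, Hoxd3, with 1 count in WT and 105 in KO. As a hypothesis, differences present on all 3 days might also arise between lines grown from single cells without regard to the edit, and with the chromosome medians subtracted 458 of the 1019 higher and 796 of the 1194 lower genes kept their calls on all 3 days. The labels do not say how many clones were used, and this was not tested.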
